A study of Homo sapiens with 12 samples.

How the data were processed

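The series holds 12 expression arrays of LNCaP cells, 3 in each of 4 groups that cross control siRNA or siRNA against SRF with R1881 or ethanol vehicle. Per the labels' protocols, cells were androgen-deprived for 48 h, transfected, and 42 h after transfection given 5 nM R1881 or vehicle for 48 h. Biotinylated cRNA was made from 3.5 µg of total RNA. The deposited values are log2 GCRMA signals, one per probe set and array, which per the submitters' processing notes were made with GCRMA; its version was not given. The scanner files were not used, and detection calls were not used here. All 12 value columns were assigned to a group from the labels.

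The table held 54675 probe sets, of which 62 were controls, 11721 had no gene symbol in the tables here, 1801 had several symbols and 41091 had 1 symbol. Of these last, 41037 were matched to current symbols through the gene number and 54 were kept as in the platform table; no symbol changed. A probe set was kept when its log2 value was above 4 on at least 3 of the 12 arrays, which left 21584, of which 18676 had 1 symbol. For the 5035 genes with more than 1 passing probe set, the probe set with the highest mean stood for the gene, so that 10265 genes were tested. Array medians ran from 2.97 to 3.06, and no further normalization was applied. Dim probe sets lay near values of 2 to 3, so a fold change against such a level depends on the background estimate of GCRMA.

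A means model of the 4 groups was fitted to the log2 values of each gene with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with moderated variances and Benjamini-Hochberg adjustment over the 10265 genes. A gene was called at an adjusted p under 0.05. The contrasts were R1881 against vehicle in control and in SRF-silenced cells, their difference (silenced minus control), and SRF siRNA against control siRNA in vehicle and in R1881. SE is the moderated standard error of a log2 change, and SD the spread of 3 arrays. A set of androgen-responsive genes was chosen on the R1881 effect averaged over both siRNAs (adjusted p under 0.05 and at least 2-fold), which favours neither siRNA. In the comparison of called genes that share the control R1881 arrays, the overlap expected with no effect was simulated 100 times with lists of the same sizes.

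The gene lists numbered 17 and held 372 genes, of which 335 had a probe set and 247 were tested: androgen-induced targets, androgen-repressed genes, SRF and actin cytoskeleton targets, immediate-early SRF targets, S phase, mitosis, cholesterol, fatty acid synthesis, ER protein folding and unfolded protein response, polyamines, integrins and focal adhesion, interferon response, neuroendocrine genes, p53 targets, and markers of basal or mesenchymal lines, of fibroblasts and of leukocytes. They were tested with camera in limma at a preset correlation between genes of 0.01 and again with the correlation estimated, with adjustment over the 80 tests. Calls over a list alone were adjusted over its members. A further 7 lists were added after the first fits and are reported in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

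Genes were named by a rule: for each contrast the 10 called genes with the largest change in each direction whose groups did not overlap (chance gives 10% for 3 against 3 arrays), with no overlap rule for the difference of effects, then members of the lists as examples, SRF, and the 10 genes of the androgen-responsive set with the smallest p for the difference. KLK3 falls outside it. The tests, the 17 lists, the naming rule and a set of alternatives were chosen before the data were examined. These alternatives changed the filter, a floor on low values, the probe set per gene, the normalization, the variance model, the arrays in the fit, a block for the replicate number and the thresholds, and left out each array in turn. Fits with the GAPDH 3-prime to 5-prime difference as a covariate and without the third array of both SRF-silenced groups, and tests of the SRF and actin cytoskeleton list without SRF, were added after seeing the data.

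RNA integrity was measured as the difference between the 3-prime and 5-prime control probe sets of GAPDH and ACTB on each array and compared by exact permutation. ACTB is itself in the SRF and actin cytoskeleton list, so GAPDH was the main measure. The fit was tested on simulated data of 10265 genes and 12 arrays, with 50 changed genes at each size. For R1881 in control cells it called 6% of genes changed by 0.25, 60% at 0.5, 96% at 1 and 98% at 2, with 10 false calls. For the difference of effects it called 2%, 24%, 90% and 100%, with 12 false calls. Far fewer genes changed in the simulation than were called in the data, which makes the adjusted p stricter there. The shares at small sizes are thus those of the simulation and may be higher in the data. A simulated list of 25 genes shifted by 0.5 was called by the camera test in limma, and 2 of 200 unchanged lists had a p under 0.05. The simulated genes were drawn independently, so this does not show how camera at the preset correlation treats correlated lists. The estimated correlation of the mitosis list, for one, was 0.273.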

Results

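Messenger RNA levels were measured in LNCaP cells, an androgen-sensitive human prostate adenocarcinoma line, on 12 Affymetrix expression arrays. The design crossed an siRNA with a hormone treatment. Cells received control siRNA or siRNA against serum response factor (SRF), a transcription factor that works with actin-sensing cofactors, and were then given R1881, a synthetic androgen, or ethanol vehicle. Each of the 4 groups held 3 arrays, which the labels call biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these arrays. The series set out to find genes that depend on both SRF and androgen, and the comparisons ask what R1881 changed with and without SRF silencing, what silencing changed with and without R1881, and whether the R1881 effect itself differed. On each array 37.3% to 38.0% of the 54675 probe sets lay above a log2 value of 4, and the array number limits the precision. Arrays of one group correlated at 0.996 to 0.998 across probe sets and arrays of different groups at 0.966 to 0.988. The first principal component held 58.7% of the variance over the 10265 genes tested and the second 29.2%.

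SRF was lower in the silenced cells under both treatments. Its mean log2 level in vehicle was 6.07 ± 0.14 (SD, n = 3) with control siRNA and 4.74 ± 0.28 (SD, n = 3) with SRF siRNA, a change of -1.34 ± 0.14 (SE) that left 39.5% of the control signal (limma adjusted p = 7.98e-06). In R1881 the levels were 6.30 ± 0.18 and 4.87 ± 0.13 (SD, n = 3 each), a change of -1.44 ± 0.14 (SE) that left 36.9% (adjusted p = 3.31e-06). SRF itself did not pass the test for R1881, with a change of 0.23 ± 0.14 (SE) in control cells. A second SRF probe set lay near background on all arrays and changed by -0.11 and -0.09 (adjusted p = 0.275 and 0.466 in a fit of all probe sets), so the knockdown rests on 1 probe set.

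**Figure D1:**
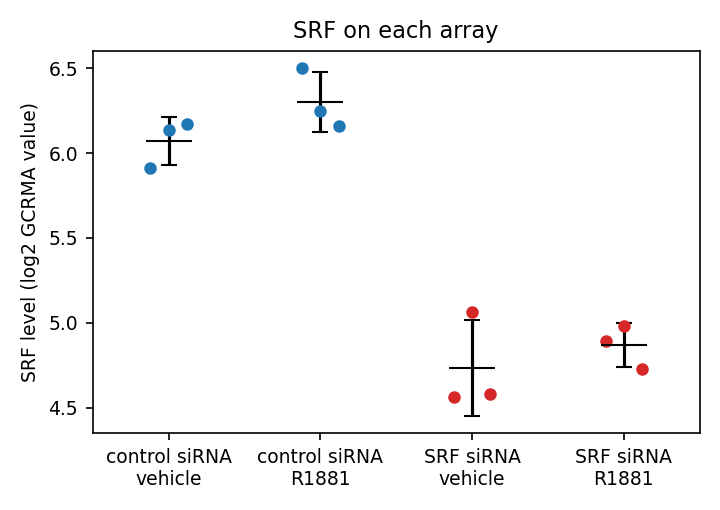
SRF level on each array, as the log2 GCRMA value of the probe set that stands for the gene (vertical axis, not starting at 0), in the 4 groups. Points are arrays, and bars are the group mean and SD (n = 3). The group means with SRF siRNA are 4.74 and 4.87 and those with control siRNA 6.07 and 6.30, with no overlap between the siRNAs.

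In control cells R1881 raised most androgen-induced targets and lowered the androgen-repressed genes. The largest rise was in HPGD, which encodes the enzyme that inactivates prostaglandin E, at 6.26 ± 0.21 on the log2 scale (SE), followed by the metalloreductase gene STEAP4 at 6.12 ± 0.19 and AFF3 at 6.09 ± 0.27. F5, SLC15A2, EAF2, NCAPD3, CCDC141, CSGALNACT1 and ANKRD37 made up the rest of the top 10, with changes of 5.16 to 6.03. The chemokine receptor gene ACKR3 fell by 6.82 ± 0.12 (SE), butyrylcholinesterase (BCHE) fell by 6.60 ± 0.23 and CAMK2N1, which encodes an inhibitor of CaM kinase II, fell by 6.49 ± 0.11. OPRK1, MMP16, ABCG2, IL1RN, LRRN1, RRM2 and PLA2G2A completed the 10 largest falls, with changes of -6.47 to -4.76. KLK3, which encodes prostate-specific antigen and was chosen after its values were seen, rose by 3.26 ± 0.06 (SE).

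Of the 36 androgen-induced targets tested, 33 rose and 2 fell, the same numbers when adjusted over the list alone. Their median change was 2.85 (camera adjusted p = 4.47e-19, and 0.00647 with an estimated correlation). All 8 androgen-repressed genes fell, also when adjusted over the list alone. Their median was -4.57 (camera adjusted p = 2.58e-08, and 0.0399 with an estimated correlation). These lists were written from general knowledge of androgen-responsive lines, LNCaP among them, so their direction is not independent evidence. Of 24 mitosis genes 22 fell and none rose (23 fell adjusted over the list alone), with the spindle genes NUSAP1 and BUB1B at -4.56 ± 0.12 and -4.18 ± 0.17 (SE). The list's median was -1.56 (camera adjusted p = 6.08e-08), a call lost at an adjusted p = 0.0924 with an estimated correlation. Of 24 S phase genes 21 fell (22 adjusted over the list alone), led by the nucleotide synthesis genes RRM2 at -4.96 ± 0.25 and TYMS at -4.18 ± 0.13. The list median was -0.93 (camera adjusted p = 6.50e-07, but adjusted p = 0.0655 with an estimated correlation).

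R1881 also raised genes of lipid synthesis and of the secretory pathway in control cells. Of 19 cholesterol synthesis and uptake genes 18 rose, also when adjusted over the list alone, with INSIG1 at 2.95 ± 0.08 and HMGCS1 at 2.34 ± 0.08. Their median was 1.26 (camera adjusted p = 8.84e-10, and 0.00647 with an estimated correlation). Of 13 fatty acid synthesis genes 9 rose and 2 fell, counts that adjusting over the list alone left as they were, led by the elongase ELOVL7 at 3.19 ± 0.09 (camera adjusted p = 0.000133, and 0.0399 with an estimated correlation). Of 28 genes of endoplasmic reticulum (ER) protein folding and the unfolded protein response, 25 rose and 1, CALR, fell, the same when adjusted over the list alone. Their median was 0.95 (camera adjusted p = 1.00e-10, and 0.0141 with an estimated correlation), led by EDEM3 at 2.51 ± 0.10 and DNAJB9 at 2.49 ± 0.08, which act in the disposal and folding of ER proteins. Integrin and focal adhesion genes rose in 8 of 12 (9 adjusted over the list alone) and fell in 1, and ITGAV was at 2.28 ± 0.11 (camera adjusted p = 0.00518, but adjusted p = 0.0655 with an estimated correlation). Immediate-early SRF targets rose in 6 of 9 and fell in 2, with the phosphatase gene DUSP5 at 3.79 ± 0.20 (camera adjusted p = 0.00826, but adjusted p = 0.0655 with an estimated correlation). Of 15 p53 targets 11 fell and 2 rose, with SESN1 at -2.55 ± 0.08 and GDF15 at 1.95 ± 0.07 (camera adjusted p = 0.0237, but adjusted p = 0.0824 with an estimated correlation). Polyamine genes moved both ways, 4 up and 3 down of 10, among them spermine synthase (SMS) at 2.55 ± 0.07 (camera adjusted p = 0.0991). For these last 3 lists the counts adjusted over the list alone were the same.

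In all, limma called 6225 of 10265 genes for R1881 in control cells, 2758 higher and 3467 lower, of which 727 and 725 changed at least 2-fold. The difference between the 3-prime and 5-prime GAPDH control probe sets, a sign of RNA integrity, was 0.14 ± 0.09 in vehicle and 0.46 ± 0.02 in R1881 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). With that difference as a covariate, chosen after seeing the data, 3924 genes were called. The measure did not overlap between vehicle and R1881, so the covariate also takes up part of the R1881 effect and its precision. Fewer calls are thus not by themselves a sign of RNA integrity. For 6 of the 10 largest rises and 7 of the 10 largest falls the lower group mean was under 4, where the size of a change depends on the background estimate.

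In SRF-silenced cells R1881 raised and lowered many of the same genes. HPGD again rose most, by 6.68 ± 0.21 (SE), followed by the sialyltransferase gene ST6GALNAC1 at 5.96 ± 0.13 and the kallikrein gene KLK2 at 5.87 ± 0.08. AKAP12, CXCL10, MYBPC1, PGC, ORM1, PTGER4 and STEAP4 rose by 5.12 to 5.60, and KLK3 by 3.54 ± 0.06. The largest falls were in the peptide hormone genes GCG, at -6.34 ± 0.27, and NTS, at -6.26 ± 0.16, followed by MAN1A1, DDC, OPRK1, ACTRT3, GRAMD1C, COL5A2, IL1RN and ACKR3 at -5.33 to -4.30.

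The androgen-induced targets rose in 32 of 36 and fell in 3, with a median of 3.11 (camera adjusted p = 3.92e-19, and 0.00647 with an estimated correlation). All 8 androgen-repressed genes fell, with a median of -3.66 (camera adjusted p = 8.32e-09, and 0.0395 with an estimated correlation). All 24 mitosis genes fell, with CENPF and CDC20 both at -2.67 and a list median of -1.75 (camera adjusted p = 3.65e-11, but adjusted p = 0.0655 with an estimated correlation). S phase genes fell in 21 of 24, with the cyclin gene CCNE2 at -2.45 ± 0.16 and a median of -0.74 (camera adjusted p = 1.31e-06, but adjusted p = 0.0655 with an estimated correlation). Cholesterol genes rose in 17 of 19, with HMGCS1 at 2.32 ± 0.08 (camera adjusted p = 8.61e-09, and 0.00647 with an estimated correlation). Fatty acid genes rose in 11 of 13 (12 adjusted over the list alone), with ELOVL7 at 3.65 ± 0.09 (camera adjusted p = 1.59e-06, and 0.0171 with an estimated correlation). ER folding genes rose in 18 of 28, with HERPUD1 at 1.63 ± 0.09 and XBP1 at 1.52 ± 0.07. Their median was 0.39 (camera adjusted p = 4.54e-05, but adjusted p = 0.0617 with an estimated correlation). Interferon response genes rose in 13 of 15 and fell in none, with IFIT2 at 1.62 ± 0.08 and the RNA sensor gene IFIH1 at 1.53 ± 0.14. Their median was 0.88 (camera adjusted p = 9.82e-06, but adjusted p = 0.0617 with an estimated correlation). Apart from the fatty acid genes, adjusting over the list alone gave the counts stated.

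In all 5453 genes were called for R1881 in silenced cells, 2614 higher and 2839 lower, of which 571 and 524 changed at least 2-fold. For 8 of the 10 largest rises and 4 of the 10 largest falls the lower group mean was under 4, where sizes and ranks depend on the background estimate. Across the 10265 genes the R1881 effects with and without silencing, which share no array, correlated at a Pearson r of 0.804 and a Spearman rho of 0.773 (genes are not independent replicates). Of the 4260 genes called in both, 4099 changed in the same direction and 161 in opposite directions.

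**Figure D2:**
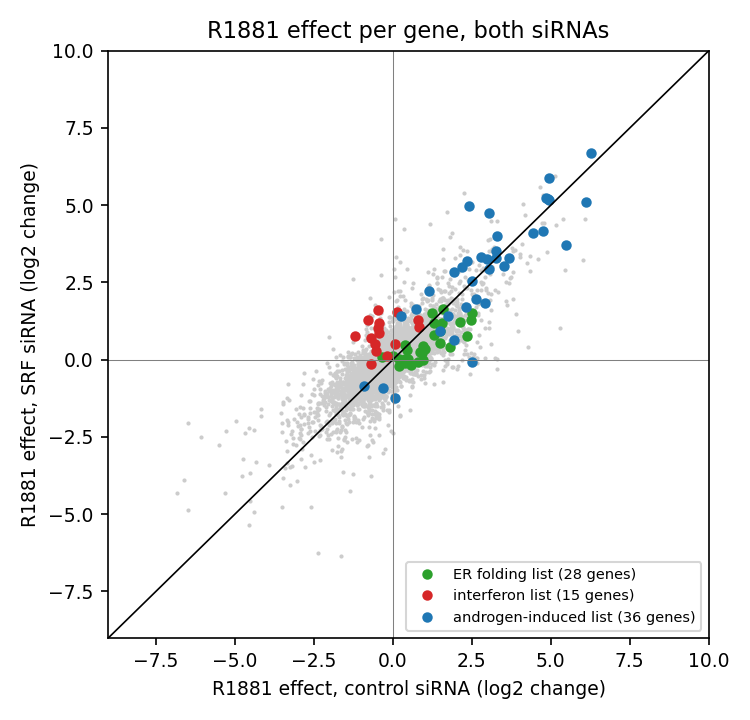
R1881 effect on each of the 10265 genes tested (grey points) with control siRNA (horizontal axis, log2 change) and SRF siRNA (vertical axis, log2 change). Coloured points are members of 3 gene lists, and the diagonal marks equal effects. The ER folding genes lie mostly below the diagonal (median difference -0.51), the interferon genes above it (median difference 1.32) and the androgen-induced targets around it (median difference 0.05).

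The R1881 effect differed between SRF-silenced and control cells for single genes in both directions and for the interferon and ER folding lists. The serpin gene SERPIND1 rose with R1881 in silenced cells alone, from 2.18 ± 0.08 to 6.74 ± 0.18 (SD, n = 3 each), against 2.22 ± 0.13 and 2.29 ± 0.05 with control siRNA, a difference of effects of 4.49 ± 0.14 (SE; adjusted p = 6.70e-09). CAMK2N1 fell by 6.49 in control cells and by 2.06 in silenced cells, a difference of 4.42 ± 0.16. SERPINE2, ZPLD1, SERHL2, MMP16, CCL20, SERPINA3, CXCL10 and TTR followed, with differences of 3.11 to 4.29. Differences below 0 were led by GCG at -4.70 ± 0.38, CSGALNACT1 at -4.25 ± 0.30, NTS at -3.90 ± 0.23, LINC00844 at -3.86 ± 0.18 and SLITRK6 at -3.60 ± 0.13, then SLC26A3, GBP1, REG4, DHRS2 and CCDC83. For GCG, NTS, REG4 and CCDC83 this was a larger fall in silenced cells, from a vehicle level that silencing had raised. GCG went from 8.69 to 2.34 with SRF siRNA and from 3.94 to 2.30 with control siRNA. The others rose with R1881 in control cells and rose less or not at all in silenced cells. Among them, CSGALNACT1 also had a vehicle level raised by silencing, from 5.09 to 8.35, with R1881 levels of 10.37 and 9.38. In the other direction, silencing had lowered the vehicle level of CXCL10 from 5.10 to 2.69 and of TTR from 6.13 to 2.70. Their R1881 levels with control and SRF siRNA were 7.35 and 8.08 for CXCL10 and 5.77 and 5.45 for TTR.

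Among the lists, the R1881 effect after silencing was lower for ER folding genes and higher for interferon genes. The difference was below 0 for 18 of 28 ER folding genes (19 adjusted over the list alone) and above 0 for 1, CALR (2 adjusted over the list alone). The median was -0.51 (camera adjusted p = 1.47e-09, and 0.0162 with an estimated correlation). SEC24D, a component of vesicle coats, was at -1.57 ± 0.24 (SE), the chaperone cofactor gene SDF2L1 at -1.41 ± 0.11 and DNAJB9 at -1.19 ± 0.11. For interferon response genes the difference was above 0 in 12 of 15 (13 adjusted over the list alone) and below 0 in none, with IFIT2 at 2.08 ± 0.12 and IFIT3 at 2.06 ± 0.15. The median was 1.32 (camera adjusted p = 8.84e-10, and 0.0203 with an estimated correlation). In control cells R1881 lowered 9 of these 15 genes and raised 2, with OASL at -1.20 ± 0.09 and OAS1 at 0.83 ± 0.13, and the list did not pass (median -0.47, camera adjusted p = 0.108).

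SRF and actin cytoskeleton targets differed in both directions, 10 of 26 lower and 4 higher, the same when adjusted over the list alone. The smooth muscle actin gene ACTA2 rose by 2.66 ± 0.09 with R1881 in control cells and stood at -0.11 ± 0.09 in silenced cells, a difference of -2.77 ± 0.13, and MYLK, the gene of myosin light chain kinase, differed by -1.99 ± 0.30. The list's median difference was -0.16 (camera adjusted p = 0.00600, but adjusted p = 0.0527 with an estimated correlation). Androgen-induced targets were split, 13 of 36 lower and 11 higher (12 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.906), with SGK1 at -2.58 ± 0.26 and SNAI2 at 2.55 ± 0.47. Of the 8 androgen-repressed genes, 6 had a higher and 1 a lower value (7 and 1 adjusted over the list alone), which for genes that fell in both states is a smaller fall. Their median was 1.56 (camera adjusted p = 5.63e-05, but adjusted p = 0.0756 with an estimated correlation). S phase genes were higher in 9 of 24 (11 adjusted over the list alone), with RRM2 at 2.99 ± 0.35 (camera adjusted p = 0.0106, but adjusted p = 0.217 with an estimated correlation). The mitosis genes split evenly, 6 higher and 6 lower of 24 (camera adjusted p = 0.906), but with values under 4 set to 4 the numbers were 5 and 10 and the list passed (median -0.35, adjusted p = 0.0439). Cholesterol genes were lower in 6 of 19 (7 adjusted over the list alone) and higher in 1, with STARD4 at -1.69 ± 0.14 (camera adjusted p = 0.00928, but adjusted p = 0.0617 with an estimated correlation).

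Limma called 2441 genes for the difference of R1881 effects, 1359 higher and 1082 lower, of which 266 and 248 differed at least 2-fold. The balance depends on the scaling: with arrays shifted to the same median it was 1220 higher and 1242 lower (243 and 275 at 2-fold), and after quantile normalization 241 and 281 differed at least 2-fold. The difference in the GAPDH 3-prime to 5-prime measure between R1881 and vehicle was 0.32 with control siRNA and 0.13 with SRF siRNA. At least 1 group mean lay under 4 for 8 of the 10 highest and 9 of the 10 lowest differences.

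For the 1178 genes whose R1881 effect averaged over both siRNAs passed the test at 2-fold or more, the response was smaller after silencing in 61.8%. The median ratio of the silenced to the control response was 0.85. A line through 0 of the silenced on the control response had a slope of 0.80, which scatter between genes also lowers. Of these 1178 genes, 623 differed between the siRNAs (697 adjusted over the set alone), 414 with a smaller and 209 with a larger response, and 7 had effects of opposite sign. The 10 with the smallest p for the difference were SERPIND1, SLITRK6, CAMK2N1, PTPRB, NCAPD3, BDNF, SLC26A3, CXCL8, CXCL10 and ACTA2. NCAPD3, a condensin gene, rose by 5.46 ± 0.07 in control cells and by 2.92 ± 0.07 in silenced cells (SE). The neurotrophin gene BDNF changed by -2.38 ± 0.07 with R1881 in silenced cells. In control cells its change was 0.00 ± 0.07, from a vehicle level near the background. The share with a smaller response depended on how the genes were chosen: it was 79.3% of 1452 genes chosen by the response in control cells and 40.5% of 1095 chosen by the response in silenced cells.

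After SRF silencing in vehicle the 10 largest rises held 3 metallothionein genes. The metallothionein genes MT1F, MT1G and MT1H, which encode metal-binding proteins, rose by 3.95 ± 0.15, 3.45 ± 0.20 and 3.24 ± 0.15 (SE). Their probe sets were not tested for signal shared between these related genes. The glucagon gene GCG rose by 4.74 ± 0.27, the lectin gene REG4 by 4.10 ± 0.13 and the neurotensin gene NTS by 3.88 ± 0.16, and CCDC83, COL5A2, CSGALNACT1 and RFX6 by 3.12 to 3.65. The melanosomal glycoprotein gene GPNMB fell most, by 4.19 ± 0.20, followed by MAP2 at -3.71 ± 0.14, TTR at -3.43 ± 0.13, PTGFR, RBM24, the chemokine receptor gene CXCR4 at -3.20 ± 0.13, LGALS8, LOC90246, PAM and TMEM134.

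Of 24 mitosis genes 23 rose after silencing in vehicle and none fell, also when adjusted over the list alone, with the kinesin gene KIF11 at 2.61 ± 0.18, CENPF at 2.37 ± 0.27 and CDC20 at 2.17 ± 0.16. Their median was 1.49 (camera adjusted p = 3.23e-09, but adjusted p = 0.0824 with an estimated correlation). S phase genes rose in 16 of 24 and fell in 2 (3 adjusted over the list alone), with UHRF1 at 1.93 ± 0.13 (camera adjusted p = 0.00245, but adjusted p = 0.154 with an estimated correlation). SRF and actin cytoskeleton targets fell in 12 of 26 and rose in 4, the same when adjusted over the list alone, with CALD1 at -1.29 ± 0.08 and MYLK at 2.29 ± 0.21 (median -0.14, camera adjusted p = 0.0582). SRF itself is 1 of the 12, and the list without it did not pass either (adjusted p = 0.0991). Androgen-induced targets fell in 18 of 36 and rose in 3 (4 adjusted over the list alone), with C1orf116 at -2.45 ± 0.11 and ACP3, which encodes prostatic acid phosphatase, at 1.96 ± 0.07 (camera adjusted p = 0.000225, but adjusted p = 0.0824 with an estimated correlation). Interferon genes fell in 7 of 15 (8 adjusted over the list alone) and rose in 2, with OASL at -2.46 ± 0.09 (median -0.28, camera adjusted p = 0.00600, but adjusted p = 0.130 with an estimated correlation). Fatty acid genes fell in 9 of 13 and rose in 1 (camera adjusted p = 0.00172, but adjusted p = 0.0617 with an estimated correlation). ER folding genes moved both ways, 9 up and 9 down of 28, with DNAJC3 at -1.66 ± 0.08 (camera adjusted p = 0.680). Of 15 p53 targets 8 rose (10 adjusted over the list alone) and 2 fell, with the cell cycle inhibitor gene CDKN1A at 1.28 ± 0.10 (camera adjusted p = 0.0297, but adjusted p = 0.0921 with an estimated correlation). The 3 neuroendocrine genes tested, ENO2, TUBB3 and NTS, all rose (camera adjusted p = 0.0129, but adjusted p = 0.0728 with an estimated correlation).

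In vehicle 5717 genes were called for silencing, 3151 higher and 2566 lower, of which 523 and 430 changed at least 2-fold. With arrays shifted to the same median the numbers were 2761 higher and 2967 lower (462 and 480 at 2-fold), and with the GAPDH covariate 1899 higher and 2042 lower of 3941, so the balance depends on the processing. For 3 of the 10 largest rises and 4 of the 10 largest falls the lower group mean was under 4. The ACTB 3-prime to 5-prime difference was 1.37 ± 0.12 with control siRNA and 1.69 ± 0.14 with SRF siRNA, and the GAPDH difference 0.14 ± 0.09 and 0.36 ± 0.04 (SD, n = 3 each; exact two-sided permutation p = 0.1 for both, the smallest possible).

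After SRF silencing in R1881 the SRF and actin cytoskeleton targets fell as a list, the one list whose call in this comparison held with an estimated correlation. CAMK2N1 rose most, by 6.22 ± 0.11 (SE), followed by the trefoil factor gene TFF1 at 5.34 ± 0.24, MT1F at 5.05 ± 0.15 and the adrenergic receptor gene ADRA2A at 4.82 ± 0.09, then MMP16, SERPIND1, RRM2, NUSAP1, MT1G and PLA2G2A at 3.96 to 4.75. GPNMB fell by 4.77 ± 0.20, TIPRL by 4.14 ± 0.23 and the secretory protein gene CRISP3 by 3.98 ± 0.23, and LINC00844, SLITRK6, AQP11, PTGFR, LINC00161, HOPX and SLC26A3 by 3.26 to 3.98.

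Of 26 SRF and actin cytoskeleton targets 17 fell and 2 rose after silencing in R1881, the same when adjusted over the list alone, with ACTA2 at -2.79 ± 0.09, SRF itself at -1.44 ± 0.14 and the calponin gene CNN2 at -1.19 ± 0.08. The list's median was -0.40 (camera adjusted p = 3.35e-05, and 0.0141 with an estimated correlation). Without SRF, the target of the siRNA, 16 of 25 fell and 2 rose, the same when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 6.91e-05, and 0.0165 with an estimated correlation). The immediate-early SRF targets did not pass as a list, with 4 up and 5 down of 9 in R1881 (median -0.39, camera adjusted p = 0.620) and 3 up and 1 down in vehicle (median 0.11, camera adjusted p = 0.465), the same when adjusted over the list alone. Mitosis genes rose in 19 of 24 (20 adjusted over the list alone) and fell in none, with NUSAP1 at 4.20 ± 0.12 and BUB1B at 3.53 ± 0.17. The list median was 1.30 (camera adjusted p = 6.63e-07, but adjusted p = 0.111 with an estimated correlation). S phase genes rose in 18 of 24, with RRM2 at 4.21 ± 0.25 (camera adjusted p = 5.43e-05, but adjusted p = 0.0921 with an estimated correlation). ER folding genes fell in 18 of 28 and rose in 4, with DNAJC3 at -2.17 ± 0.08 and a median of -0.33 (camera adjusted p = 1.87e-05, but adjusted p = 0.0527 with an estimated correlation). Interferon genes rose in 11 of 15 and fell in 1, OASL, with IFI27 at 2.47 ± 0.24 (camera adjusted p = 0.00783, but adjusted p = 0.141 with an estimated correlation). Androgen-induced targets fell in 24 of 36 and rose in 5 (7 adjusted over the list alone), with EAF2 at -2.10 ± 0.15 and SNAI2 at 2.75 ± 0.33 (camera adjusted p = 5.94e-05, but adjusted p = 0.0728 with an estimated correlation). Of 15 p53 targets 11 rose and 2 fell, with the repair gene DDB2 at 2.19 ± 0.12 (camera adjusted p = 0.00616, but adjusted p = 0.0617 with an estimated correlation). For markers of other cell types, 0 of 15 leukocyte genes, 3 of 15 fibroblast genes and 2 of 18 basal or mesenchymal genes passed the filter on dim probe sets. Of the 3 fibroblast genes, COL1A1, COL3A1 and FN1, 2 rose and none fell (1 fell adjusted over the list alone), with a median of 1.11 (camera adjusted p = 0.332). Both basal or mesenchymal genes, ANXA1 and VIM, rose by 1.98 and 1.93 (camera adjusted p = 0.0353, but adjusted p = 0.0934 with an estimated correlation).

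In R1881 6058 genes were called for silencing, 3452 higher and 2606 lower, of which 689 and 503 changed at least 2-fold. With arrays shifted to the same median 2898 were higher and 3168 lower (561 and 619 at 2-fold). For 5 of the 10 largest rises and 6 of the 10 largest falls the lower group mean was under 4. The silencing effects in vehicle and in R1881, which share no array, correlated at r = 0.705 and rho = 0.719 across genes, and of 4231 genes called in both, 3956 moved in the same direction. The ACTB 3-prime to 5-prime difference was higher by 0.31 with SRF siRNA, where it was 1.81 ± 0.35 (SD, n = 3; exact two-sided permutation p = 0.1). The GAPDH difference was 0.46 ± 0.02 and 0.49 ± 0.14 (exact p = 0.8).

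**Figure D3:**
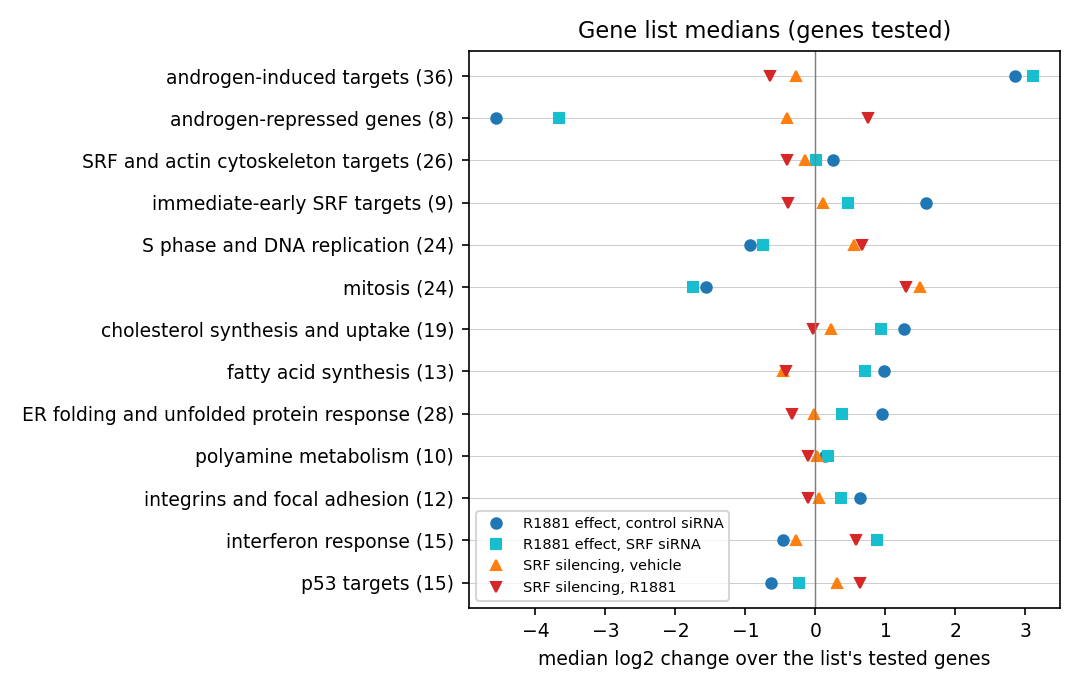
Median log2 change (horizontal axis) over the tested genes of each list with 8 or more of them (vertical axis, number of genes in parentheses), for the R1881 effect with each siRNA and for SRF silencing with each treatment. The mitosis list lies at -1.56 and -1.75 for R1881 and at 1.49 and 1.30 for silencing, and the interferon list at -0.47 and 0.88 for R1881.

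Genes that R1881 raised in control cells and that were lower after silencing in R1881 numbered 1348, and genes that R1881 lowered and that were higher after silencing numbered 1812. ACTA2, EAF2, SLITRK6 and SLC26A3 belonged to the first set and CAMK2N1, MMP16, RRM2 and NUSAP1 to the second. Both comparisons use the control R1881 arrays. Independent lists of these sizes would share 700.2 and 1166 genes. With no effect at all and lists of the same sizes, the shared arrays alone gave a mean of 1323 (highest 1365 in 100 simulations) for the first set and 1916 (highest 1979) for the second, so neither observed number lay above the simulated highest. In the same simulations no gene passed both tests, so they cannot tell how much of either set comes from the shared arrays. The 3 control R1881 arrays were too few to split between the comparisons. With the GAPDH covariate the first set held 870 genes.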

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

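The tests of RNA integrity and of a general siRNA response, the splits of the 4 pairwise comparisons and the NF-kappa-B list were chosen after the results were seen, while the matched lists and the regroupings for the difference and for the overlap were written before. The results of this part are those where the R1881 effect differed between SRF-silenced and control cells by the test of the difference itself.

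Interferon response genes had a higher R1881 effect after silencing, with a median difference of 1.32. RNA integrity as the whole cause is argued against: the 3-prime to 5-prime measures of GAPDH and ACTB were higher with SRF siRNA by 0.22 and 0.32 in vehicle and by 0.03 and 0.31 in R1881, the GAPDH value in R1881 within the spread of the arrays. The list mean changed by -0.50 ± 0.06 (SE, from the spread between arrays) after silencing in vehicle and by 0.64 ± 0.06 in R1881. ACTB is itself in the SRF target list, so its measure may move with SRF. The list mean also rose in R1881, where the GAPDH measure hardly differed between the siRNAs. In vehicle 7 of 15 interferon genes fell and 2 rose, with a median of -0.28. The list did not pass there with an estimated correlation (camera adjusted p = 0.130). The lack of a rise in vehicle still argues against an interferon response that the SRF siRNA raises whatever the treatment. A response to the siRNA that needs androgen, an off-target effect of the siRNA and an effect of SRF itself stay open and were not tested.

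ER folding genes had a lower R1881 effect after silencing, with a median difference of -0.51. Their list mean changed by -0.044 ± 0.02 (SE) after silencing in vehicle, where both 3-prime to 5-prime measures rose at least as far as in R1881, and by -0.57 in R1881, which argues against RNA integrity as the whole cause. A general weakening of R1881 responses is argued against as well, since 0% of 10000 lists matched on average R1881 effect and level had a median as low (matched median -0.12, lowest -0.42). The matched genes were drawn independently, without the correlation within the ER folding list (estimated at 0.0488), so the share of 0% is too firm. The pattern extended to vesicle transport genes (median difference -0.44), on the same arrays and with the same siRNA, so an effect of SRF and an off-target effect of the siRNA both stay open.

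The difference was called for 2441 genes, and 1 of 100 regroupings of the residuals of an additive fit, the real one, gave as many (highest other 4). A random assignment of the arrays to the groups is thus argued against at that level. The regroupings cannot tell the treatments from a difference between the cultures of each group, since the labels do not say how the replicates were made. For the overlap of 1348 genes raised by R1881 and lower after silencing, 4 of 100 regroupings of the 9 arrays gave as large an overlap (highest other 1850). This says nothing about how the effects are related, since 94 of the 99 other regroupings shared 0 genes. With no effect and lists of the same sizes the shared arrays gave up to 1365 genes, but no gene passed both tests in those simulations. They held no real effects, so they cannot tell how many of the 1348 genes come from the shared arrays. The 10 splits of 6 arrays are too few for a share under 0.05 in the other comparisons, where the real split, 1 of 10 to give as many, called 6225 (R1881 in control cells, highest other 0), 5453 (R1881 in silenced cells, highest other 0), 5717 (silencing in vehicle, highest other 0) and 6058 genes (silencing in R1881, highest other 1).

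Other results that differed by the same test at the preset correlation are given as values. The list medians were 1.56 for androgen-repressed genes, -0.16 for SRF and actin cytoskeleton targets, 0.41 for S phase genes, -0.18 for cholesterol genes, -0.44 for the 3 neuroendocrine genes and 1.08 for the 2 basal or mesenchymal markers. With an estimated correlation none of these 6 lists passed (adjusted p = 0.0756, 0.0527, 0.217, 0.0617, 0.0795 and 0.0924 in that order). The highest differences were SERPIND1 4.49, CAMK2N1 4.42, SERPINE2 4.29, ZPLD1 3.88, SERHL2 3.88, MMP16 3.57, CCL20 3.22, SERPINA3 3.21, CXCL10 3.15 and TTR 3.11. The lowest were GCG -4.70, CSGALNACT1 -4.25, NTS -3.90, LINC00844 -3.86, SLITRK6 -3.60, SLC26A3 -3.28, GBP1 -3.16, REG4 -3.07, DHRS2 -3.05 and CCDC83 -2.89. In the androgen-responsive set PTPRB was at -2.63, NCAPD3 at -2.54, BDNF at -2.39, CXCL8 at 2.61 and ACTA2 at -2.77.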

How the results depend on the processing

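The fits with the GAPDH covariate and without the last replicate of both SRF-silenced groups, and the SRF target list without SRF, were chosen after the data were seen. Over 80 list medians, 1753 of 1845 alternative values kept direction and side of the threshold. A change of sign occurred in 39 values of 18 lists and contrasts, of which 1 had passed its test. For 680 named gene and contrast pairs 14937 of 15478 were kept, and 176 values of 71 pairs changed sign, 2 of them for pairs that had passed. For the 11 main results 251 of 279 were kept. Most of these are counts or a share, which cannot change sign, and the SRF changes kept theirs. A count was kept when it stayed within a set ratio of its main value. The share was kept when it stayed within the spread of the fits with one array left out. Testing every probe set gave 10501 and 9018 calls for R1881 in control and silenced cells, 9437 and 10178 for silencing in vehicle and R1881, and overlaps of 2283 and 2804. Requiring 2-fold as well left 1452, 1095, 514, 953 and 1192 calls in the 5 contrasts (R1881 in control cells, in silenced cells, their difference, silencing in vehicle, in R1881) and overlaps of 197 and 233. The difference fell to 1367 calls at an adjusted p under 0.01. With the GAPDH covariate R1881 in control cells gave 3924 calls, silencing in vehicle 3941 (1899 higher and 2042 lower, against 3151 and 2566), the difference 1911 (1187 higher and 724 lower) and the overlap 870. The covariate moved the median of all genes for R1881 in control cells to -0.128. Its values did not overlap between the groups of R1881 in control cells, nor between those of silencing in vehicle. Fewer calls there can thus be a loss of precision and are not by themselves a sign of RNA integrity. The replicate block gave 6148, 5316, 2200, 5585 and 5921 calls, and 18 pairs of arrays with the same number had residual correlations of -0.214 to 0.0994, 0 of them over 0.1, so the numbers were not used as pairs. Without that replicate of both SRF-silenced groups the counts were 6297, 4692, 1898, 5213 and 5593.

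The second SRF probe set changed by -0.11 (adjusted p = 0.275) in vehicle and -0.088 (adjusted p = 0.466) in R1881. The share of responsive genes with a smaller response after silencing (61.8%) was 62.9% with a filter at 5, 60.3% after quantile normalization, 62.6% after median scaling, 65.0% with the GAPDH covariate, 79.3% and 40.5% when chosen by the response in control or in silenced cells, and 61.0% to 63.2% with one array left out. With an estimated correlation the mitosis medians of 1.49 and 1.30 after silencing in vehicle and in R1881 did not pass (adjusted p = 0.0824 and 0.111). Median scaling moved the share of higher genes among those called from 57.0% to 47.8% for silencing in R1881, from 55.1% to 48.2% for silencing in vehicle and from 55.7% to 49.6% for the difference, and quantile normalization moved them to 50.5%, 50.3% and 52.6%. Which direction held more genes thus depends on the scaling. The mitosis median for the difference of effects also changed sign, to -0.06 after quantile normalization and to -0.35 with values under 4 set to 4, where it passed (adjusted p = 0.0439, against up to 0.999 over its alternatives). Called values that changed sign were the neuroendocrine list for R1881 in silenced cells without a filter (0.0059), AZIN1 for R1881 in control cells with the GAPDH covariate (0.163) and PTK2 for silencing in R1881 with the mean of probe sets (-0.252), and the cause was not tested.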

Other observations

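Lists for antigen presentation and vesicle transport were written before those genes were looked at and the NF-kappa-B and metallothionein lists after some of their genes were seen, all after the first fits, with adjustment over 35 tests. The higher R1881 effect on interferon genes after silencing extended to antigen presentation, with a difference above 0 for 12 of 14 genes and below 0 for none, among them TAP2 at 1.54 ± 0.27 (SE), and a median of 0.72 (camera adjusted p = 1.94e-06, and 0.0267 with an estimated correlation). It came with NF-kappa-B targets. Without CXCL8, which prompted this list, 4 of 8 were higher and none lower (5 higher adjusted over the list alone), RELB at 2.15 ± 0.21, with a median of 0.82 (camera adjusted p = 0.00239, and 0.0481 with an estimated correlation). With control siRNA R1881 already raised 6 of these 8 genes and lowered 1, among them TNFAIP3 at 4.12 ± 0.28. Of the 14 antigen presentation genes it raised 3 and lowered 6 with control siRNA (median -0.255, camera adjusted p = 0.434). In silenced cells it raised 11 and lowered none (median 0.51, camera adjusted p = 0.000684, but adjusted p = 0.0523 with an estimated correlation). The median of the interferon list turned from -0.47 with control siRNA to 0.88 in silenced cells, which is not a larger response in the same direction. The interferon-induced gene GBP1, outside these lists, went the other way, with a difference of -3.16 ± 0.20 (SE). A candidate explanation is a wider inflammatory programme whose R1881 effect is higher after this siRNA, through SRF or an off-target effect. A second siRNA against SRF, and RNA sensor knockdown in the same design, would test it.

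The lower effect on ER folding genes extended to transport vesicles between ER and Golgi, lower for 16 of 26 genes and higher for none (19 lower adjusted over the list alone), SEC24B at -0.90 ± 0.12, with a median of -0.44 (camera adjusted p = 6.33e-08, and 0.0357 with an estimated correlation). Translocation and N-glycosylation genes were lower in 17 of 22 (20 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 8.84e-10, and 0.0399 with an estimated correlation). Aminoacyl-tRNA synthetases, 2 lower and 1 higher of 17, did not pass (median -0.01, camera adjusted p = 0.614), and only 1 of 22 gut and liver genes was tested. In silenced cells R1881 still raised 16 of the 26 vesicle genes and lowered none (median 0.26, against 0.71 in control cells), and it raised 11 of the 22 translocation genes and lowered 2. Both lists passed there at the preset correlation (camera adjusted p = 4.04e-05 and 0.045), but neither with an estimated correlation (adjusted p = 0.0528 and 0.46). Some members had no called difference, such as SPCS3 at 1.54 ± 0.10 and 1.74 ± 0.10. SRF, or an off-target of the siRNA, may thus contribute to the size of the androgen induction of many secretory pathway genes, which measuring protein secretion with a second siRNA would test.

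All 6 metallothionein genes tested rose after silencing, with medians of 3.16 in vehicle and 3.60 in R1881. Whether their probe sets tell these related genes apart was not tested, so the 6 rises may not be separate. The list passed at the preset correlation (camera adjusted p = 6.84e-06 and 1.06e-05), but not with an estimated correlation (adjusted p = 0.0523 in both), and 4 of the genes had prompted it. The other 2, MT1X and MT1E, rose by 2.99 ± 0.09 and 1.30 ± 0.16 (SE) in vehicle (camera adjusted p = 0.0255, but adjusted p = 0.106 with an estimated correlation). Both also rose in R1881 (camera adjusted p = 0.0265, but adjusted p = 0.106 with an estimated correlation). The measured fall of SRF rests on a probe set of low signal, with means after silencing of 4.74 in vehicle and 4.87 in R1881. It is thus an uncertain yardstick. In both treatments 93 genes fell at least as far as this measured fall, among them GPNMB, PTGFR, TIPRL and KAT2B. The labels give neither sequence nor number of the siRNAs, so direct off-target silencing of some of these genes was not tested, and a change common to both treatments is not by itself an effect of SRF.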
